A study of Mus musculus with 8 samples.

How the data were processed

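Total RNA from 3 sorted mouse bone marrow populations was amplified, labelled with biotin and hybridised to single-colour microarrays. Per the labels, RNA was extracted with Trizol and prepared with the Ovation Pico WTA V2 and Encore Biotin kits, which amplify small amounts of RNA. Per the submitters' processing notes, the values were made with RMA, which corrects background, normalizes arrays to a common distribution and summarises the probes of a probe set. The RMA version, the software and the probe annotation behind it were not given in the sources used here. The deposited table held log2 values for 33649 probe sets on 8 arrays, with 1 column per array. The log2 scale was read from the values, which ran from about 2 to 13, since no source states it. Such values compress differences of dim probe sets, and an amplification step before labelling can add spread between arrays. The array medians lay between 4.95 and 5.22 and the interquartile ranges between 2.49 and 3.06, so the arrays' distributions were close but not identical. No raw signals over background were analysed here, and the small number of arrays limits the precision.

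Gene names came from the platform's annotation. Of the 33649 probe sets, 23521 had 1 gene symbol, 1814 had several and 8314 were unnamed here. Probe sets with several symbols were left unnamed. The named probe sets covered 22180 genes, of which 1082 had more than 1 probe set and were represented by the one with the highest mean over all arrays. Genes entered the tests when their mean over all arrays reached the 25th percentile of all probe sets, a log2 value of 3.88, which left 17576 genes. Genomic positions were not used here.

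Samples were grouped by population from the sample titles and markers in the labels. All 8 arrays entered 1 linear model in limma 3.58.1 under R 4.3.3, with a mean per population and a spread shared by all populations, since LT-HSC had only 2 arrays. The residual degrees of freedom were 5 and the prior degrees of freedom from eBayes were 5.93. The 3 pairwise contrasts and the F test over all populations were adjusted by the Benjamini-Hochberg method over the 17576 genes, and a gene was called at an adjusted p under 0.05. The p-values called limma adjusted p below come from this model. Chd7 was also tested by exact two-sided permutation of the array labels. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over 23 lists, and again with an estimated correlation and with fry. Camera compares a list with all other genes, whereas fry asks whether its members move, on balance, one way.

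The design, the 23 lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists were the sort gate, the CHD family, chromatin remodelers other than CHD, core-binding factors and partners, HSC identity, lymphoid priming, myeloid priming and megakaryocyte-erythroid priming. Further lists covered the cell cycle, CDK inhibitors and quiescence regulators, immediate early genes, ribosome biogenesis and MYC targets, oxidative phosphorylation, glycolysis, the interferon response, MHC class II, and cell adhesion and cytoskeleton. Markers of other cell types formed the B cell, T and NK cell, granulocyte and monocyte, erythroid, and stroma and endothelium lists, and ubiquitous control genes formed the last. Of 596 list entries, 548 matched a gene, 3 of these through another symbol, and 535 were tested. Entries without a match here included Ly6a, which encodes Sca1, and the globin genes, so the erythroid list kept 3 tested genes.

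Named genes followed a fixed rule. It took the CHD family and the sort gate genes in every comparison. It took, per comparison, the 10 largest increases and the 10 largest decreases among called genes whose groups did not overlap. Symbols of predicted genes, clones, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments were left out. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were given as values. It also allowed up to 6 called members of each list and up to 2 members that were not called, the most highly expressed ones.

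Replicate numbers are shared between populations in the labels, so a check asked whether arrays with the same number deviated together from their group means. For ST-HSC and MPP the correlations of these deviations over all genes were 0.15, 0.23 and 0.21 for replicates 1, 2 and 3. All 3 exceeded 0.1, so the numbers were taken to pair these arrays, and a fit with the replicate number as a block is given beside that comparison. Arrays of these populations with different numbers gave -0.28 to 0.07. Deviations from a group mean cancel within a population, so positive values for shared numbers force the others lower on balance. The latter are therefore no separate evidence of pairing. The check is weak, since 3 arrays per population can be matched in few ways and the labels state no pairing. The block fit also included the LT-HSC arrays. LT-HSC shares only 2 numbers with the other populations, too few for this rule.

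Alternatives were no filter and a filter at the 50th percentile, the mean of a gene's probe sets, quantile normalization again, and centring each array on its median. Others were a trended and robust eBayes prior, array weights, only the 2 groups compared, the replicate block, a minimum fold change of 2, all probe sets, and leaving out each array in turn. Leaving out an LT-HSC array leaves a lone sample that is assumed to vary like the other groups. Without LT-HSC replicate 3 that sample is replicate 1, the array of narrowest interquartile range. Passes and counts in that setting therefore rest on this array alone. Omission of the 2 arrays that stood apart, the array's interquartile range as a covariate, and the replicate block with only 2 groups were added after the data were seen. The pipeline was tested on simulated data in which 200 of 17576 genes were changed. At a log2 difference of 1 it recovered 35 of 67 changed genes for MPP against LT-HSC, 36 of 67 for ST-HSC against LT-HSC and 48 of 67 for MPP against ST-HSC. At 2 it recovered 66 of 66 in each comparison. At 0.5 it recovered 2, 0 and 5 of 67, so differences of that size mostly went uncalled, and 13 of 116, 3 of 105 and 13 of 132 calls were false. The simulated noise was independent between genes and of equal spread in all arrays. The real arrays had weights from 0.40 to 3.83, and cell cycle genes an estimated correlation of 0.68. Recovery and false calls in the real data may therefore differ from these shares. Figures were drawn with Python 3.11.15, pandas 2.3.3 and Matplotlib 3.10.9.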

Results

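Expression was measured on 8 microarrays of hematopoietic stem and progenitor cells sorted from the bone marrow of C57/Bl6 mice, given in the labels as 8 weeks old. Long-term hematopoietic stem cells (LT-HSC, 2 arrays, replicates 1 and 3) were gated as CD48-negative, CD150-positive and CD34-negative. Short-term hematopoietic stem cells (ST-HSC, 3 arrays) differed from these in being CD34-positive. Multipotent progenitors (MPP, 3 arrays) were CD48-positive, CD150-negative and CD34-positive. All 3 populations lacked lineage markers and carried Sca1 and Kit. The labels conflict on treatment: the descriptions state none, whereas the shared protocol describes DMSO for 2 hours and passage through transplanted recipients for 1 year and then 3 months. Values are log2 RMA signals, and differences are differences of log2 means with limma's standard error (SE). The labels do not say that arrays came from separate animals, so p-values measure only the spread between these samples, which may be technical.

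Slamf1, which encodes the gate marker CD150, was 7.77 ± 0.01 (SD, n = 2) in LT-HSC, 7.34 ± 0.11 (SD, n = 3) in ST-HSC and 5.06 ± 0.36 (SD, n = 3) in MPP. It was lower in MPP than in LT-HSC by a log2 difference of -2.72 (limma adjusted p = 0.00115) and than in ST-HSC by -2.28 (limma adjusted p = 0.00218). Its ST-HSC minus LT-HSC difference was -0.43 (limma adjusted p = 0.484). Cd34 was 9.35 ± 1.20, 9.92 ± 0.33 and 10.92 ± 0.08 (SD) in LT-HSC, ST-HSC and MPP, with the LT-HSC arrays at 8.50 in replicate 1 and 10.20 in replicate 3. None of its contrasts passed (limma adjusted p = 0.194 for MPP minus LT-HSC, 0.62 for ST-HSC minus LT-HSC and 0.456 for MPP minus ST-HSC). Without LT-HSC replicate 3, Cd34 passed in MPP minus LT-HSC (limma adjusted p = 0.00794) and in ST-HSC minus LT-HSC (limma adjusted p = 0.0226), where the values over all alternatives ran from 0.00794 to 0.759 and from 0.0226 to 0.996. In MPP minus ST-HSC, where Cd34 differed by 1.00, it passed with array weights (limma adjusted p = 0.0263) and with only the 2 groups in the replicate block (0.0236), within a range of 0.0236 to 1. Without LT-HSC replicate 1, its ST-HSC minus LT-HSC difference of 0.57 turned to -0.28. Cd48 averaged 6.28 ± 0.50, 6.86 ± 0.55 and 7.15 ± 0.62, and Kit 10.26 ± 0.01, 10.14 ± 0.29 and 10.29 ± 0.23. As a list, the sort gate genes passed in no comparison (camera adjusted p = 0.725, 0.972 and 0.605), and they are gate markers rather than findings. Their medians of 0.45, 0.23 and 0.22 were positive while camera's direction was lower in each comparison, and their means were -0.06, 0.15 and -0.21.

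LT-HSC replicate 1 and ST-HSC replicate 1 stood apart from the other arrays, with median correlations of 0.956 and 0.968 and narrow interquartile ranges of 2.49 and 2.73. Markers of mature granulocytes were high in the replicate 1 array of each population. S100a8, a neutrophil protein, was 11.09 in LT-HSC replicate 1 and 6.61 in replicate 3, and 11.29, 9.32 and 8.26 in ST-HSC replicates 1, 2 and 3. In MPP it was 10.60, 9.53 and 9.86. Relative to their mean over all arrays, the granulocyte and monocyte genes were 0.89, 1.17 and 0.60 in the replicate 1 arrays of LT-HSC, ST-HSC and MPP, and between -0.96 and -0.28 in all others. The erythroid genes were 0.31, 0.96 and 0.44 in the replicate 1 arrays and between -0.52 and -0.04 in the others. Stroma and endothelium genes stood at 0.33, 1.45 and 0.22 in the replicate 1 arrays and between -0.47 and -0.24 in the others. None of these lists differed between populations by camera, with adjusted p from 0.332 to 0.972 for erythroid genes, 0.472 to 0.972 for granulocyte and monocyte genes and 0.194 to 0.972 for stroma and endothelium genes.

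By mean signal, Chd7, an ATP-dependent chromatin remodeler of the chromodomain helicase family, was highest in LT-HSC, intermediate in ST-HSC and lowest in MPP. No difference passed the threshold over all genes. The question set by the series is how Chd7 is expressed across these populations. Its probe set, 17411647 (Entrez gene 320790), read 5.66 and 5.81 in the LT-HSC arrays, 5.16, 5.20 and 5.18 in the ST-HSC arrays and 5.02, 4.95 and 4.99 in the MPP arrays. The means were 5.74 ± 0.11 (SD, n = 2), 5.18 ± 0.02 (SD, n = 3) and 4.99 ± 0.04 (SD, n = 3). Over all arrays Chd7 lay at the 53.5th percentile of probe sets, a low level here. The lists of B cell genes and of T and NK cell genes mark cells that the lineage gate would remove. They averaged 4.63 to 5.08 and 4.96 to 5.30 across arrays, so Chd7 in ST-HSC and MPP lay near that level. No array of one population overlapped another. The log2 differences were -0.75 for MPP minus LT-HSC (SE 0.16, limma adjusted p = 0.153) and -0.55 for ST-HSC minus LT-HSC (SE 0.16, limma adjusted p = 0.186). For MPP minus ST-HSC the difference was -0.20 (SE 0.14, limma adjusted p = 0.981). None of the 3 passed the threshold over 17576 genes, and neither did the F test over all populations (limma adjusted p = 0.111). Tested alone by exact permutation of the array labels, the F statistic gave p = 0.00357, the smallest this design allows. Each pairwise exact permutation test gave p = 0.1, again the smallest possible, so no pairwise comparison of 2 or 3 arrays against 3 could pass 0.05 in that way.

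Among the 10 CHD family genes, Chd7 was the only one with a negative MPP minus LT-HSC difference in the deposited values and after median centring, and Chd9 joined it at -0.04 with quantile normalization. This contrast leaned on LT-HSC replicate 1, the array of narrowest range. Relative to all arrays, the family's mean was -0.27 there and 0.14 in LT-HSC replicate 3, against 0.11, 0.14 and 0.09 in MPP. In LT-HSC replicate 3, Chd1l at 6.80 exceeded all MPP arrays (6.76, 6.61 and 6.72). Chd3 at 10.70 lay below all of them (10.87, 11.13 and 11.09). Adjusted over the list alone, Chd7 passed as lower in MPP and in ST-HSC than in LT-HSC. In MPP against ST-HSC, Chd3, a subunit of the nucleosome remodeling and deacetylase complex, passed as higher when adjusted over the list alone. Chd3 was 10.44 ± 0.36, 10.39 ± 0.07 and 11.03 ± 0.14 (SD) in LT-HSC, ST-HSC and MPP. Its MPP minus LT-HSC difference of 0.59 had a limma adjusted p of 0.343, or 0.0493 without LT-HSC replicate 3 (the lowest of its alternatives, which reached 1), and its MPP minus ST-HSC difference of 0.64 had 0.231, or 0.0111 with array weights, with alternatives from 0.0111 to 0.791. Chd4, of the same complex, was 9.67 ± 0.10, 9.67 ± 0.10 and 9.79 ± 0.07. The ST-HSC minus LT-HSC differences were positive for 5 of the 10 genes, but for 2 with quantile normalization and 7 with median centring, while MPP minus ST-HSC was positive for 8 of 10 under all 3 scalings. As a list the family passed in no comparison (camera adjusted p = 0.32, 0.754 and 0.0731).

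**Figure D1:**
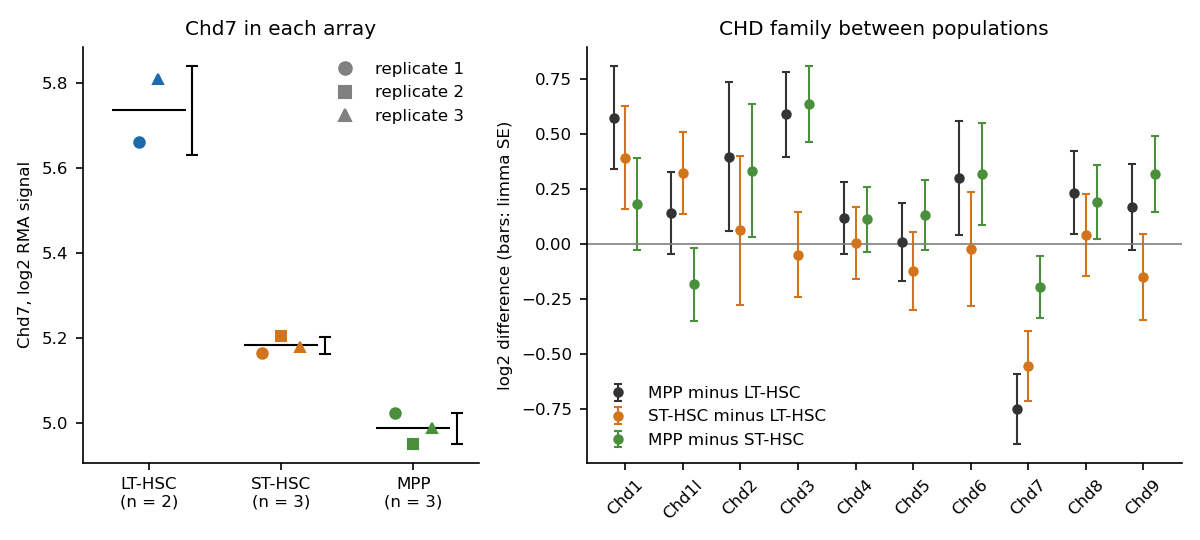
Left, log2 RMA signal of Chd7 in each of the 8 arrays by population, with symbols for replicates, lines for means and bars for SD. Right, log2 differences of the 10 CHD family genes with limma SE for the 3 comparisons. Chd7 lies between 5.66 and 5.81 in LT-HSC and between 4.95 and 5.02 in MPP, and no difference passes an adjusted p of 0.05.

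Against LT-HSC, 6 of 42 tested HSC identity genes fell in MPP (the list had adjusted p = 0.452 with an estimated correlation). Sult1a1, a phenol sulfotransferase, was 8.94 ± 0.52 (SD, n = 2) in LT-HSC and 6.27 ± 0.14 (SD, n = 3) in MPP, 6.35-fold lower (log2 difference -2.67, SE 0.29, limma adjusted p = 0.00554). Vwf, the platelet adhesion protein von Willebrand factor, differed by -1.82 (SE 0.24, limma adjusted p = 0.0147), and the imprinted long noncoding RNA Meg3 by -1.88 (SE 0.18, limma adjusted p = 0.00249). The 6 were Sult1a1, Vwf, the receptor Neo1 (-1.57), the transglutaminase Tgm2 (-1.44), the catenin-like Ctnnal1 (-1.37) and the stress-induced regulator Nupr1 (-1.34). The secreted semaphorin Sema3d was the only gene that rose, by 1.54 (SE 0.24, limma adjusted p = 0.0387). Highly expressed HSC identity genes that did not pass were Ifitm3 (-0.10, limma adjusted p = 0.81) and Cd81 (0.03, limma adjusted p = 0.963).

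In all, 22 of 17576 genes differed between MPP and LT-HSC, 1 higher and 21 lower in MPP, with 1856 at an unadjusted p under 0.05 where chance gives 879. The groups did not overlap for 24.7% of genes, where chance gives 20%. Besides Slamf1, the largest decreases included the focal adhesion protein Tns2 (-2.05), the smoothelin-like Smtnl1 (-2.02), guanine deaminase Gda (-1.95), the growth factor Pdgfc (-1.70), Slfn2 (-1.70) and the adhesion molecule Ncam2 (-1.59). Since fewer than 5 genes rose, those with the next smallest p are given as values that did not pass. They were the metalloproteinase Mmp2 (1.37, limma adjusted p = 0.0726), the tetraspanin Cd37 (1.30, limma adjusted p = 0.0776), the kinetochore gene Ndc80 (1.15, limma adjusted p = 0.0875), Tespa1 (1.77, limma adjusted p = 0.0958) and Satb1 (1.32, limma adjusted p = 0.097). Mmp2 and Cd37 passed without ST-HSC replicate 1 (limma adjusted p = 0.0178 and 0.0292). Without LT-HSC replicate 3, LT-HSC is replicate 1 alone, an array that stood apart, so fits in that setting compare MPP against that array. Over all alternatives their adjusted p lay between 0.00982 and 0.378. The count of 22 became 615 without LT-HSC replicate 3, 11 without LT-HSC replicate 1, 34 without ST-HSC replicate 1, and 7, 11 and 6 without MPP replicates 1, 2 and 3. Of the 15 named called genes, Slamf1, Sult1a1, Tns2, Smtnl1 and Meg3 kept their call whichever array was left out. The others lost it in some omissions, at adjusted p between 0.0516 and 0.241, with 10 lost without MPP replicate 3, 9 and 6 without MPP replicates 1 and 2, 7 without LT-HSC replicate 1, and 4 and 2 without ST-HSC replicates 2 and 3. Called HSC identity genes numbered 2 lower without LT-HSC replicate 1, 4 without ST-HSC replicate 2, 1 without each MPP array, and 7 lower and 1 higher without LT-HSC replicate 3, where 13 cell cycle genes were called higher. Centring each array on its median shifted the median difference over all genes by 0.12 here, by 0.11 in ST-HSC minus LT-HSC and by 0.01 in MPP minus ST-HSC, and left 5 genes here, none higher.

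By camera, 8 of 23 lists separated MPP from LT-HSC. With an estimated correlation 0 did (0 at an unadjusted p under 0.05), and by fry 0 did (4 at an unadjusted p under 0.05). HSC identity genes were lower, with a median of -0.43 (camera adjusted p = 4.23e-15, adjusted p = 0.452 with an estimated correlation), and 18 were lower and 1 higher when adjusted over the list alone. Megakaryocyte-erythroid priming genes were lower, with a median of -0.28 over 26 genes (camera adjusted p = 0.000146, adjusted p = 0.452 with an estimated correlation), and Vwf was the member that fell; adjusted over the list alone 3 were lower and 1 higher. Cell cycle genes were higher, with a median of 0.64 and 81 of 82 positive (camera adjusted p = 6.54e-28, adjusted p = 0.452 with an estimated correlation). None of the 82 was called by limma over all genes, but 49 were when adjusted over the list alone, with the replication clamp Pcna at 0.26 and the helicase subunit Mcm6 at 0.52 (limma adjusted p = 0.59 and 0.444). Myeloid priming genes were higher, with a median of 0.32 over 30 genes (camera adjusted p = 4.56e-05, adjusted p = 0.452 with an estimated correlation) and 8 called when adjusted over the list alone. Myeloperoxidase, Mpo, differed by 0.53 and lysozyme, Lyz2, by -0.13 (limma adjusted p = 0.527 and 0.77), and 11 of the 30 members were, like the granulocyte markers, highest in replicate 1 of every population. Lymphoid priming genes were higher, with a median of 0.27 over 22 genes (camera adjusted p = 0.0206, adjusted p = 0.587 with an estimated correlation) and 4 called when adjusted over the list alone. Among them the transcription factors Sox4 (1.00, limma adjusted p = 0.2, with alternatives from 0.0429 without LT-HSC replicate 3 to 0.939) and Mef2c (0.53, limma adjusted p = 0.512) did not pass.

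Chromatin remodelers other than CHD (median 0.32), ribosome biogenesis and MYC targets (0.26) and oxidative phosphorylation genes (0.20) were also higher in MPP than in LT-HSC by camera. Their camera adjusted p was 0.000146, 0.000142 and 0.000309, and adjusted p = 0.717, 0.717 and 0.775 with an estimated correlation; adjusted over the list alone, 0 members passed by limma in any of them, as over all genes. These 3 calls were lost without LT-HSC replicate 1, the array of narrowest range, at medians of 0.06, 0.07 and 0.05 (camera adjusted p = 0.399, 0.0952 and 0.269), and with both arrays that stood apart left out (0.369, 0.139 and 0.286). The myeloid call was lost without LT-HSC replicate 3 (camera adjusted p = 0.0587), and the lymphoid call without LT-HSC replicate 1 (0.0771), MPP replicates 1 and 2 (0.0537 and 0.0555) and both arrays that stood apart (0.0791), and with array weights (0.0622). The interquartile range as a covariate gave the chromatin list 0.127, and the filter at the 50th percentile gave oxidative phosphorylation 0.066. With quantile normalization the lymphoid, chromatin and ribosome lists had a camera adjusted p of 0.0856 and oxidative phosphorylation 0.386, and median centring gave the lymphoid list 0.0629. Ubiquitous control genes had a median of 0.35 with 11 of 12 positive, or 9 with quantile normalization and 12 with median centring (camera adjusted p = 0.0553). Their median exceeded those of the myeloid (0.32) and lymphoid priming lists (0.27) and of the chromatin, ribosome and oxidative phosphorylation lists. Medians of that size were therefore not particular to these lists. Lists that did not pass were CDK inhibitors and quiescence regulators (camera adjusted p = 0.18), core-binding factors and partners (0.34), immediate early genes (0.781), glycolysis (0.203), the interferon response (0.0699), MHC class II (0.544), cell adhesion and cytoskeleton (0.32), B cell (0.0749) and T and NK cell genes (0.222).

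**Figure D2:**
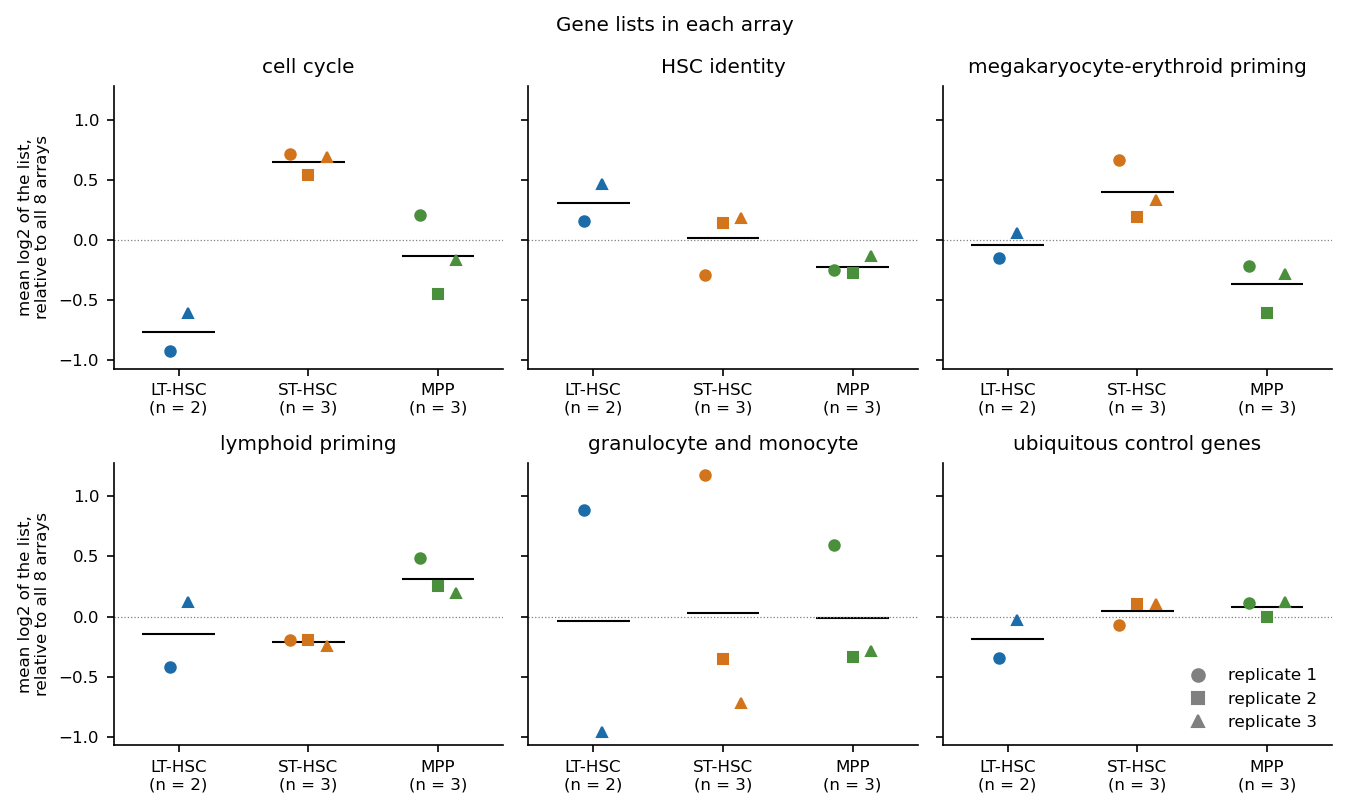
Mean log2 signal of 6 gene lists in each array, relative to the list's mean over all 8 arrays, by population; symbols mark replicates and lines are means. Cell cycle genes lie between 0.54 and 0.71 in ST-HSC and between -0.92 and -0.61 in LT-HSC, and granulocyte and monocyte genes are highest in the replicate 1 array of each population.

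Of 82 tested cell cycle genes 58 rose in ST-HSC against LT-HSC by limma over all genes, and 81 when adjusted over the list alone. The list had adjusted p = 0.339 with an estimated correlation, and all 82 differences were positive, with a median of 1.45. The spindle checkpoint kinase Bub1 was 5.94 ± 0.26 (SD, n = 2) in LT-HSC and 8.03 ± 0.10 (SD, n = 3) in ST-HSC, 4.25-fold higher (log2 difference 2.09, SE 0.23, limma adjusted p = 0.0043). The kinetochore genes Nuf2 (2.12), Knl1 (2.04) and Ndc80 (2.01), the mitotic entry phosphatase Cdc25c (2.04) and the kinesin Kif15 (2.01) rose by similar amounts. Pcna and Mcm6, the most highly expressed members outside the calls, had differences of 0.42 and 0.75 (limma adjusted p = 0.423 and 0.188). The list passed by camera (adjusted p = 1e-88) and by fry (adjusted p = 0.0238).

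Overall 164 of 17576 genes differed between ST-HSC and LT-HSC, 149 higher and 15 lower in ST-HSC, with 1943 at an unadjusted p under 0.05 where chance gives 879, and 23.3% of genes without overlap where chance gives 20%. Outside the cell cycle list, large increases included the kinetochore gene Ska3 (2.40, SE 0.23, limma adjusted p = 0.00401), the cytokinesis gene Cep55 (2.18), Depdc1a (2.17) and the linker histone H1f1 (2.13). Genes that fell included Sult1a1 (-1.66), Tns2 (-1.52), Smtnl1 (-1.52), Meg3 (-1.50), Pdgfc (-1.50), Ncam2 (-1.45) and Neo1 (-1.12). Gbp9 (-1.25), a guanylate-binding protein, the noncoding RNA Rian (-1.12), from the same imprinted cluster as Meg3, and the metalloproteinase Mmp16 (-1.04) also fell. The count of 164 became 825 without LT-HSC replicate 3, 17 without LT-HSC replicate 1, 109, 94 and 53 without ST-HSC replicates 1, 2 and 3, and 84 without MPP replicate 3. With both arrays that stood apart left out, limma called 0 genes, and 1348 had an unadjusted p under 0.05. Called cell cycle genes then numbered 0, with a median of 1.28 that was positive in all 82, against 7 without LT-HSC replicate 1 alone and 29 without ST-HSC replicate 3. Of the 24 named called genes, Ska3, Cep55, Cdc25c, Ndc80, Smtnl1, Meg3 and Ncam2 kept their call whichever array was left out. The others lost it in some omissions, at adjusted p between 0.0507 and 0.398: 17 without LT-HSC replicate 1, 2 without LT-HSC replicate 3, 6, 5 and 11 without ST-HSC replicates 1, 2 and 3, and 2 and 9 without MPP replicates 1 and 3. Median centring left 104 genes, 98 higher and 6 lower.

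Besides the cell cycle, 5 lists separated ST-HSC from LT-HSC by camera. Megakaryocyte-erythroid priming genes were higher, with a median of 0.33 over 26 genes (camera adjusted p = 0.000331, adjusted p = 0.707 with an estimated correlation). The list stood at 0.67 in ST-HSC replicate 1 against 0.19 and 0.33 in replicates 2 and 3, and 6 of the 26 members were highest in replicate 1 of every population. Of its members, the platelet glycoprotein Gp5 rose by 1.44 (SE 0.24, limma adjusted p = 0.0194) and the integrin Itga2b, known as CD41, by 1.18 (SE 0.17, limma adjusted p = 0.00814). Adjusted over the list alone, 4 were higher and 1 lower, and the carbonic anhydrases Car2 (0.20) and Car1 (0.39) did not pass. HSC identity genes were lower, with a median of -0.27 (camera adjusted p = 5.88e-07, adjusted p = 0.707 with an estimated correlation), Sult1a1 and Neo1 fell, and 6 of 42 were lower when adjusted over the list alone. Ribosome biogenesis and MYC targets (median 0.37, camera adjusted p = 1.1e-08) and oxidative phosphorylation genes (median 0.33, camera adjusted p = 1.46e-10) were higher, each with adjusted p = 0.707 with an estimated correlation and with 0 members called by limma over all genes or adjusted over the list alone. Chromatin remodelers other than CHD were higher, with a median of 0.22 (camera adjusted p = 0.00807, adjusted p = 0.924 with an estimated correlation). Of these, Hells, a remodeler needed for DNA methylation, rose by 1.16 (SE 0.21, limma adjusted p = 0.0263), and 2 of 28 were higher when adjusted over the list alone.

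The chromatin call between ST-HSC and LT-HSC was lost without LT-HSC replicate 1 (camera adjusted p = 0.954), without ST-HSC replicate 2 (0.052) and with quantile normalization (0.665). It was also lost with the filter at the 50th percentile (0.082), with the interquartile range as a covariate (0.544) and with both arrays that stood apart left out (0.639), as was the megakaryocyte-erythroid call with the latter (median 0.13, 0.0623). Without LT-HSC replicate 1 the medians of the chromatin, ribosome and oxidative phosphorylation lists were 0.01, 0.20 and 0.18, and the HSC identity median lay between -0.49 and -0.16 leaving out each array. Of the called HSC identity genes, 0 were left by limma without LT-HSC replicate 1, ST-HSC replicate 3 or MPP replicate 3, and 1 without LT-HSC replicate 3 or ST-HSC replicate 1. The count of 6 lists became 10 without LT-HSC replicate 1 and without ST-HSC replicate 1. With an estimated correlation 0 lists passed (1 at an unadjusted p under 0.05). The inhibitor Cdkn2c rose by 1.35 (SE 0.27, limma adjusted p = 0.0468) among CDK inhibitors and quiescence regulators, of which 3 of 19 were higher when adjusted over the list alone, but that list did not pass (camera adjusted p = 0.534). Further lists that did not pass were immediate early genes (camera adjusted p = 0.0549), myeloid priming (0.172), lymphoid priming (0.177), core-binding factors and partners (0.786), glycolysis (0.582), the interferon response (0.506), MHC class II (0.972), cell adhesion and cytoskeleton (0.507), B cell (0.115), T and NK cell (0.595) and ubiquitous control genes (0.0986, with a median of 0.18 and 10 of 12 positive). The median and mean differed in sign for core-binding factors (-0.06 and 0.03), MHC class II (-0.09 and 0.04) and T and NK cell genes (-0.09 and 0.00). Camera's direction was lower, against positive medians, for granulocyte and monocyte (0.02), erythroid (0.20) and stroma and endothelium genes (0.08).

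In MPP against ST-HSC, 4 of 26 megakaryocyte-erythroid priming genes and 4 of 82 cell cycle genes fell, and 1 of 22 lymphoid priming genes rose. These lists had adjusted p = 0.106, 0.203 and 0.203 with an estimated correlation. Cavin2, a caveola protein abundant in platelets, was 6.79 ± 0.25 (SD, n = 3) in ST-HSC and 4.55 ± 0.09 (SD, n = 3) in MPP, 4.72-fold lower (log2 difference -2.24, SE 0.28, limma adjusted p = 0.0141). Platelet factor Pf4 (4.01-fold lower, limma adjusted p = 0.034), Gp5 (-1.81) and Itga2b (-1.17) also fell, and 13 of that list did when adjusted over the list alone. Satb1, a chromatin organiser active in lymphoid cells, rose from 5.23 ± 0.09 to 6.98 ± 0.24 (SD), 3.36-fold (log2 difference 1.75, SE 0.22, limma adjusted p = 0.0141). It was the lymphoid priming gene called, and 5 were higher when adjusted over the list alone. Cell cycle genes had negative differences in all 82 members, with a median of -0.85, and the cohesin acetyltransferase Esco2 (-1.22), shugoshin Sgo1 (-1.15) and the spindle genes Nusap1 (-1.12) and Prc1 (-1.10) fell, or 72 members when adjusted over the list alone.

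Between MPP and ST-HSC 34 of 17576 genes differed, 12 higher and 22 lower in MPP, with 1211 at an unadjusted p under 0.05 where chance gives 879, and 14.2% of genes without overlap where chance gives 10%. With the replicate number as a block, 267 genes were called, 126 higher and 141 lower, and all 34 were among them. With median centring 1 gene was called, 0 higher and 1 lower, with 894 at an unadjusted p under 0.05. Other increases were Tespa1 (1.88), a T cell signaling gene, Sema3d (1.78), the interleukin receptor Il10ra (1.74), the purinergic receptor P2ry10 (1.58), the lectin Cd33 (1.38), Emp1 (1.21), the inhibitory receptor Btla (1.02) and the actin-binding Ablim1 (0.97). Other decreases were the retinaldehyde dehydrogenase Aldh1a1 (-1.71), the sphingosine-1-phosphate transporter Mfsd2b (-1.69), Nupr1 (-1.50), the growth factor Ptn (-1.39), Bex4 (-1.35) and Gda (-1.33). The count of 34 became 71 without either LT-HSC array, 19, 2 and 1 without ST-HSC replicates 1, 2 and 3, and 20, 1 and 1 without MPP replicates 1, 2 and 3. Of the 24 named called genes, Slamf1 kept its call whichever array was left out. The others lost it in some omissions, at adjusted p between 0.0548 and 0.288, with 11, 22 and 23 lost without ST-HSC replicates 1, 2 and 3 and 11, 23 and 23 without MPP replicates 1, 2 and 3. Called cell cycle genes numbered 9 without either LT-HSC array, 6 without MPP replicate 1 and 0 without any other array. Called megakaryocyte-erythroid genes numbered 3, 1 and 0 without ST-HSC replicates 1, 2 and 3 and 2, 0 and 0 without MPP replicates 1, 2 and 3.

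By camera, 9 of 23 lists separated MPP from ST-HSC. With an estimated correlation 0 did (3 at an unadjusted p under 0.05), and by fry 0 did (4 at an unadjusted p under 0.05). Cell cycle genes were lower (camera adjusted p = 6.34e-75, adjusted p = 0.203 with an estimated correlation), with 42 lower in the replicate block. Megakaryocyte-erythroid priming genes were lower, with a median of -0.76 (camera adjusted p = 6.37e-20, adjusted p = 0.106 with an estimated correlation), 11 of them lower in the replicate block. Lymphoid priming genes were higher, with a median of 0.36 (camera adjusted p = 6.74e-07, adjusted p = 0.203 with an estimated correlation) and 4 higher in the replicate block. Sox4, a transcription factor of early lymphoid cells, differed by 0.97 (limma adjusted p = 0.141, or 0.0194 in the replicate block, with alternatives from 0.0118 to 0.438) and Mef2c by 0.45 (limma adjusted p = 0.859). HSC identity genes were lower, with a median of -0.17 (camera adjusted p = 5.01e-05, adjusted p = 0.753 with an estimated correlation) that lay between -0.38 and -0.07 leaving out each array. Nupr1 was the member that fell over all genes, 14 were lower and 4 higher when adjusted over the list alone, and 11 were lower and 1 higher in the replicate block.

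Myeloid priming genes were higher in MPP than in ST-HSC, with a median of 0.13 (camera adjusted p = 0.001, adjusted p = 0.646 with an estimated correlation), 0 of 30 called by limma over all genes, 7 when adjusted over the list alone and 4 higher in the replicate block. Interferon response genes were higher, with a median of 0.27 (camera adjusted p = 8.86e-05, adjusted p = 0.753 with an estimated correlation), 0 of 29 called by limma over all genes, 1 when adjusted over the list alone and 3 higher in the replicate block. Immediate early genes were higher, with a median of 0.43 (camera adjusted p = 0.001, adjusted p = 0.753 with an estimated correlation) with 0 of 26 called by limma over all genes or adjusted over the list alone and 1 higher in the replicate block. Ribosome biogenesis and MYC targets (median -0.13, camera adjusted p = 0.0222) and oxidative phosphorylation genes (median -0.13, camera adjusted p = 0.000118) were lower, each with adjusted p = 0.753 with an estimated correlation and 0 members called by limma over all genes or adjusted over the list alone. The immediate early call was lost without ST-HSC replicate 1 (camera adjusted p = 0.803) and both arrays that stood apart (0.81), the myeloid call without ST-HSC replicate 3 (0.0524) and MPP replicate 1 (0.0929), and the ribosome call without ST-HSC replicates 1 and 3 (0.0673 and 0.113) and MPP replicate 2 (0.716) and with array weights (0.0775). Lists that did not pass were chromatin remodelers other than CHD (camera adjusted p = 0.332), core-binding factors and partners (0.0975), CDK inhibitors and quiescence regulators (0.746), glycolysis (0.567), MHC class II (0.276), cell adhesion and cytoskeleton (0.802), B cell (0.941), T and NK cell (0.521) and ubiquitous control genes (0.802). In the replicate block 1 CDK inhibitor and 1 glycolysis gene were higher. Stroma and endothelium genes did not pass without the block (camera adjusted p = 0.194) and were lower with it (0.0175, adjusted p = 0.76 with an estimated correlation). ST-HSC replicate 1 stood at 1.45 for this list against -0.43 and -0.44 in replicates 2 and 3. The granulocyte and monocyte list had a median of 0.00 above its mean of -0.04, with camera's direction lower.

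**Figure D3:**
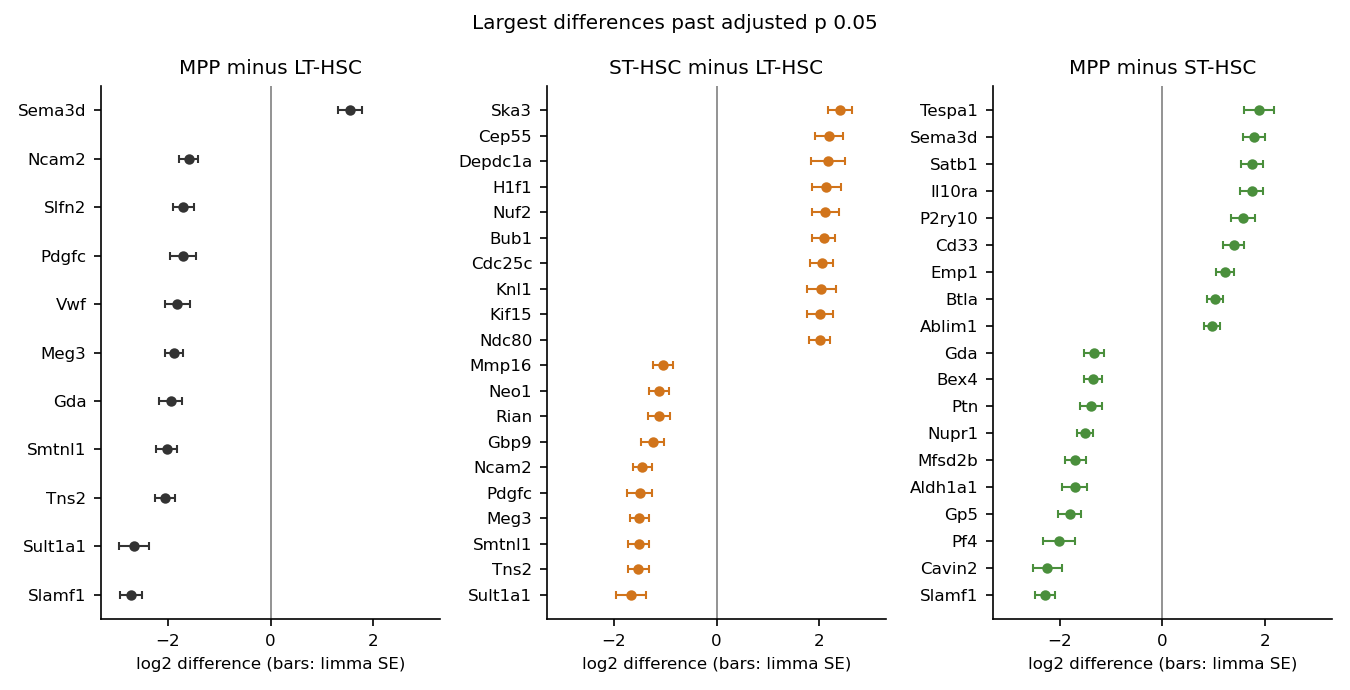
Log2 differences of the named genes with the largest changes among those past an adjusted p of 0.05, 1 panel per comparison, with limma SE as bars. Sult1a1 lies at -2.67 and -1.66 in the comparisons with LT-HSC, Ska3 at 2.40 in ST-HSC minus LT-HSC and Cavin2 at -2.24 in MPP minus ST-HSC.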

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

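Omission of the arrays that stood apart, the interquartile range as a covariate and the replicate block with only 2 groups were tests chosen after the data were seen. Chd7 kept its sign and stayed outside the threshold in every alternative run. Leaving out each array gave Chd7 differences of -0.82 to -0.67 for MPP minus LT-HSC, -0.63 to -0.48 for ST-HSC minus LT-HSC and -0.21 to -0.18 for MPP minus ST-HSC, with an F test adjusted p of 0.107 to 0.334. Over all alternatives the limma adjusted p of these differences lay between 0.0613 and 0.461, 0.0964 and 0.576, and 0.403 and 1. The cause was not tested for any of the changes below, except that all probe sets adds tests and an omission removes arrays. For MPP against LT-HSC, 22 genes became 37 with quantile normalization, 5 with median centring, 9 with array weights, 157 with the replicate block, 47 with the interquartile range and 13 with all probe sets, and 6 to 615 leaving out each array. For ST-HSC against LT-HSC, 164 became 104 with median centring, 61 with array weights, 100 with only the 2 groups, 473 with the replicate block and 83 with all probe sets, and 17 to 825 leaving out each array. Limma called 0 there with both arrays that stood apart left out, with 1348 at an unadjusted p under 0.05, while the cell cycle list passed by camera (adjusted p = 2.05e-74) but had p = 0.0582 with an estimated correlation. For MPP against ST-HSC, 34 became 1 with median centring, 525 with array weights, 71 with only the 2 groups, 267 with the replicate block, 289 with both of these, 78 with both arrays that stood apart left out, 197 with the interquartile range and 1 with all probe sets, and 1 to 71 leaving out each array.

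Over all populations, 159 genes by the F test became 65 with median centring, 386 with array weights, 566 with the replicate block, 88 with both arrays that stood apart left out, 276 with the interquartile range and 40 with all probe sets, and 29 to 520 leaving out each array. Lists called for MPP against LT-HSC, 8, became 4 with quantile normalization, 5 with both arrays that stood apart left out, and 0 with an estimated correlation or fry (0 and 4 at an unadjusted p under 0.05), with 5 to 10 leaving out each array. For ST-HSC against LT-HSC, 6 became 12 with the interquartile range, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 1 with fry, with 6 to 10 leaving out each array. For MPP against ST-HSC, 9 became 0 with an estimated correlation or fry (3 and 4 at an unadjusted p under 0.05), with 8 to 13 leaving out each array. The Cd34 difference between ST-HSC and LT-HSC turned to -0.276 without LT-HSC replicate 1, with 1.425 as the highest value leaving out an array, and turned to -0.088 with both arrays that stood apart left out. Called named genes stayed past the threshold in 586 results under alternatives and fell short in 123, and in 301 and 203 when an array was left out. Calls between MPP and ST-HSC that the replicate block changed, for Sox4, the stroma list and the numbers of genes and list members, are given with the comparison. LT-HSC shares only 2 numbers with each other population, with correlations of 0.54 and 0.47 with ST-HSC and -0.16 and 0.099 with MPP, so its replicate block values are given only here. In that fit camera called 8 lists for ST-HSC against LT-HSC, the 6 without the block and immediate early genes, lower (adjusted p = 6.17e-05), and myeloid priming genes, higher (0.0186), each with adjusted p = 0.727 with an estimated correlation. By fry the cell cycle list there had an adjusted p of 0.113, so the fry call was lost, and 0 lists passed. For MPP against LT-HSC the 8 lists called were the same. Leaving out each array, medians for MPP minus LT-HSC lay between 0.15 and 0.55 (lymphoid) and -0.39 and -0.15 (megakaryocyte-erythroid). For MPP minus ST-HSC they lay between 0.08 and 0.69 (immediate early), 0.06 and 0.20 (myeloid) and -0.20 and -0.02 (ribosome). Signal over background was not analysed here, and the number of arrays limits the precision.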

Other observations

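The tests chosen only after the result was seen were those of the arrays that stood apart, of a shared batch, of mature cells in ST-HSC by 2 groups of lists, of the replicate block in the splits, of Slamf1 and of the 12 genes higher in MPP; the spread allowed for mature cell lists and the estimated correlation asked of the imprinted genes were also added after values were seen, and the further neutrophil genes were chosen after the replicate 1 pattern was seen but before their own values were.

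Meg3 and Rian, maternally expressed noncoding RNAs of 1 imprinted cluster, were higher in LT-HSC. Rian was 5.66 in LT-HSC, 4.54 in ST-HSC and 4.32 in MPP, and it fell by 1.34 in MPP against LT-HSC (limma adjusted p = 0.0438). That call was not run through the alternatives. In ST-HSC against LT-HSC, Rian lost its call in 6 of the 8 omissions of an array and with median centring. Meg3 kept its call in both comparisons whichever array was left out. The hypothesis that imprinted genes as a group are higher in LT-HSC was tested on 28 other imprinted genes whose values had not been seen when the set was written, with Ndn left out as already seen. Their median MPP minus LT-HSC difference was -0.08, 18 were negative, and limma called 0. Among them, Cdkn1c (-0.75) is also in the HSC identity list, which camera called lower in MPP. Dcn (0.34) is also in the stroma and endothelium list, so the set is not fully separate from lists tested earlier. Camera gave p = 0.00633, which met the bound set beforehand, but p = 0.0619 with an estimated correlation, so the hypothesis may hold and is left open.

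Cell cycle genes were higher in ST-HSC than in both other populations, by medians of 1.45 and 0.85. The arrays that stood apart do not account for the size of these medians. Without them the medians were 1.28 and 0.78, each with all 82 members positive, the lower ratio to all arrays being 0.881. LT-HSC is then replicate 3 alone, so the 1.28 rests on a single LT-HSC array. This compares sizes only and does not show that the differences exceed the spread between arrays. Genes of B, T or NK cells, which the lineage gate would remove, showed no matching rise. By the rule used here a list of theirs would need to reach 0.43. The higher reached -0.0921, or 0.313 with the members' SD added. Both lists lay at a dim level, where differences are compressed, so these values cannot exclude such cells. Granulocytes, monocytes or erythroid cells, which the lineage gate would also remove, stay open by this rule. The higher of their lists, of 3 erythroid genes, reached 0.197 with an upper bound of 0.261 from a bootstrap over genes, below the 0.43 needed. With the members' SD added it reached 0.446, and granulocyte and monocyte genes 0.449. Relative to all arrays, granulocyte and monocyte genes were 0.89 in LT-HSC replicate 1, where cell cycle genes were -0.92. In ST-HSC replicates 2 and 3 they were -0.36 and -0.72, where cell cycle genes were 0.54 and 0.69. These values argue against granulocytes and monocytes for those 3 arrays, whereas in ST-HSC replicate 1 both lists were high (1.17 and 0.71). Megakaryocyte-erythroid primed cells remain possible, since that list's lower median was 0.328 with a 75th percentile of 0.70, and a difference in cycling between the populations was not tested apart from these.

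Flt3, a receptor of lymphoid-primed progenitors, was 5.84 in LT-HSC replicate 1 and 8.49 in replicate 3, against 7.07 in ST-HSC and 9.56 in MPP, and Cd34 also differed between the LT-HSC arrays. The Flt3 difference lay at percentile 100 of genes of a like level, and the Cd34 difference of 1.70 exceeded the upper bound of 1.43 for such genes. The shift shared by genes of a like level was thus smaller than these differences. Since both genes were examined for differing between these same 2 arrays, their rank cannot decide whether the narrow signal range of replicate 1 contributes. MPP cells in replicate 3, which the LT-HSC gate would remove, may be a source: Flt3 would need 43.5% of MPP RNA, and 12 genes higher in MPP than in ST-HSC had a median difference of 0.43 (bootstrap 0.06 to 0.73) after subtracting genes of a like level, 9 of them above 0. Slamf1, which that share would lower by 0.66, differed by 0.01 where genes of a like level had a median of 0.51, so relative to these it was lower, whereas 16 genes lower in MPP than in ST-HSC had a median difference of 0.296 (bootstrap -0.05 to 0.69), above the bound of -0.41 set beforehand. That bound was wrong, since these genes are not absent from MPP and would drop by only -0.27, and after subtracting genes of a like level the median was -0.03 (-0.43 to 0.34), which leaves it open. Bootstrap bounds in this paragraph resample genes, so they show the spread between genes and not between arrays.

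Markers of granulocytes and some other mature cells were highest in the replicate 1 array of each population, as seen in 13 of 15 granulocyte and monocyte genes, 3 of 3 erythroid, 5 of 11 stroma and endothelium, 11 of 30 myeloid priming and 6 of 26 megakaryocyte-erythroid priming genes, but 1 of 6 B cell and 0 of 11 T and NK cell genes, against 4.89% of all genes. A narrow signal range cannot be the source in MPP replicate 1, whose interquartile range was 3.05 against 2.82 and 2.97 in MPP replicates 2 and 3. There the granulocyte list lay at percentile 100 of 10000 random lists. Since the list was examined for being high in that array, this rank decides nothing. For LT-HSC and ST-HSC replicate 1, with narrow ranges of 2.49 and 2.73, a contribution of the range stays open. RNA of mature neutrophils, which the lineage gate would remove, may be a source: of 30 further neutrophil genes 11 (36.7%, exact binomial bounds 19.9% to 56.1%) were highest in replicate 1 of all 3 populations, more than of all genes but fewer than the share of 50% set beforehand, so it stays open. The binomial bounds treat genes as independent, although all were read from the same arrays. A shared batch also stays open, since the replicate 1 deviations correlated at 0.54, -0.159 and 0.15 and those of 2 LT-HSC arrays mirror each other. No biological explanation was tested, and neither was RNA of erythroid or stromal cells.

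For the 34 genes that differed between MPP and ST-HSC, 1 of the 10 splits of the 6 arrays, the real one, gave as many, and the highest of the others gave 0 by limma, without the block. Of the 4 splits that part all 3 replicate pairs, the real one gave 267 with the replicate block and the others 0. The splits are too few for a share under 0.05.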
